A study of Arabidopsis thaliana with 8 samples.

How the data were processed

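The data are one table of 22810 probe sets by 8 arrays, from cell cultures whose titles name them fum (4 arrays) or met (4 arrays). The submitters' processing notes name MAS5, with no version, and the table holds the signal values that the authors deposited for each array. These signal values are linear, and the mean of each array over the values between its 2nd and 98th percentile was about 100, as scaling of each array to one target gives. No further step by the authors, such as a background setting, is given in the sources used here. Detection calls were not used here. MAS5 works on each array alone. Its low signals are noisy, and log2 differences of dim probe sets carry large errors.

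Probe sets were named through the annotation table supplied with the data, which pairs 13513 probe sets with 1 gene and 503 with several, and lists no gene for 8794. Symbols were updated by gene identifier through the RefSeq gene table of the TAIR10.1 assembly, where 13436 of the 13513 matched. No probe set with several genes was given a name. The annotation is old, and many well-known genes have no probe set of their own in it. Of 488 distinct loci in the gene lists, 81 had their own probe set and 63 were tested. The array's genome build is not given in the sources used here, so no coordinates are given and the assembly served only for names and gene order.

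For the analysis, 93 values of 0 were raised to 0.1, the smallest positive signal, and signals were taken to log2 with no pseudocount and no further normalization. The 64 control probe sets were left out, and a probe set was tested where its mean log2 signal over all arrays was above the 40th percentile, equal to a signal of 21.1. This left 13647 probe sets and, with the brightest unshared probe set of each gene, 7471 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with group as the only term, two-sided, with Benjamini-Hochberg adjustment over all probe sets tested. A probe set passed at an adjusted p under 0.05. Folds are ratios of geometric means, and means ± SD are of linear signals.

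The gene lists (26, of which 4 are markers of other cell types) were written before the data were examined. A list with at least 5 tested members was tested as a set with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 3 lists so tested, and again with an estimated correlation and with fry. Named genes follow a rule also fixed then. It takes the 10 largest rises and 10 largest falls among genes that passed and whose groups did not overlap, up to 3 members of each list with the smallest p, and all tested members of the metacaspase, developmental cell death and housekeeping lists. DTX3 and a few genes in the closing section lie outside the rule and were chosen after their values were seen.

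Array quality was read from 11 measures, among them 3′ to 5′ ratios of actin, GAPDH and ubiquitin controls, the 25S ribosomal RNA probe set, 8 hybridization control probe sets and the signal of organelle-encoded genes. Each was compared with an exact permutation test over all 70 assignments of arrays to groups, on the log scale.

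Alternatives were quantile normalization, centring on the array median, 16 added to each signal, no filter, a filter at the 60th percentile, eBayes without the trend or with a robust fit, array weights, the replicate number as a block, leaving out each array in turn, and for lists an estimated correlation and the mean of all probe sets of a gene. Alternatives on the 25S signal were added after seeing the data. The procedure was tested on simulated arrays with the means and spread of the 13647 probe sets, with 200 changed in each of 10 runs. It recovered 19.5% of changes of 0.5 on the log2 scale, 70.1% of changes of 1 and 94.4% of changes of 2, with 4.95% false calls. In the list test over 7471 genes, a set of 12 genes shifted by 0.4 had p below 0.05 in 10 of 10 runs, and 1.5% of unchanged sets did. Estimated correlations in the real lists were 0.17 for proteases, 0.26 for autophagy and -0.01 for sphingolipid metabolism. Where they lie above the preset 0.01, these list rates may not hold. A difference of 0.5 on the log2 scale is thus often missed at this number of arrays.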

Results

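Total RNA from Arabidopsis thaliana cell cultures of the Landsberg erecta background (Ler) was labelled with biotin and measured on 8 expression arrays. The cultures were kept at 24 °C in Murashige and Skoog medium with sucrose, the synthetic auxin NAA and the cytokinin kinetin. The titles divide the arrays into 4 named fum and 4 named met, numbered 1 to 4 in each group. The labels expand neither name and call neither group a control, so every difference is given as fum relative to met. The series title places the comparison in a search for genes at the core of plant programmed cell death. Nothing in the labels says that arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The median deposited signal lay between 33.1 and 41.45 on the 8 arrays, and the number of arrays limits the precision.

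Comparing fum with met asked which transcripts differed between these groups of cell cultures. The strongest rise of a named gene was that of AT1G56060, at 855 ± 188 signal units (SD, n = 4) in fum and 160.4 ± 45.6 in met. This was a 5.40-fold difference (log2 2.43, SE 0.20, limma adjusted p = 0.000272). CYP71B22, a cytochrome P450, rose 5.07-fold, from 82.9 ± 42.5 in met to 395 ± 93.4 in fum (adjusted p = 0.00223). AT1G24140, of the matrix metalloproteinase family, rose 4.05-fold to 124.7 ± 12.2 (adjusted p = 0.000967). AT1G26380, an oxidoreductase of the berberine bridge enzyme family, rose 3.31-fold (log2 1.73, SE 0.33, adjusted p = 0.0214). AT1G50590 rose 3.21-fold, the zinc finger gene AT2G28710 2.91-fold and AT1G19020 2.84-fold. AT1G19020 reached 879 ± 89.0 in fum against 311 ± 43.9 in met. The glutathione transferase gene GSTU25 rose 2.83-fold, from 37.75 ± 9.31 to 110.9 ± 42.0. AT2G22620 and the beta-glucosidase gene BGLU25 completed the 10 largest rises, at 2.44-fold and 2.38-fold. Their met means of 17.35 and 18.3 lay below the signal of 21.1 that served as the filter, and with 16 added to each signal their log2 differences fell from 1.28 and 1.25 to 0.78 each.

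Some of these calls did not hold when 1 array was left out. AT1G26380 did not pass without fum replicate 1, 3 or 4 or without met replicate 3 or 4 (adjusted p up to 0.0826, log2 1.48 to 2.09 over all omissions). GSTU25 did not pass without replicate 4 of either group (adjusted p up to 0.0683, log2 1.32 to 1.71). AT2G22620 passed on 7 arrays only when met replicate 2 was the array left out (adjusted p up to 0.111, log2 1.13 to 1.52). BGLU25 passed only when fum replicate 1 or met replicate 3 was left out (adjusted p up to 0.163, log2 1.10 to 1.46).

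The deepest fall of a named gene was that of AT3G48640, from 68.0 ± 19.1 in met to 12.9 ± 5.45 in fum (SD, n = 4). The signal was 5.65-fold higher in met (log2 -2.50, SE 0.37, limma adjusted p = 0.00682). AT5G22555 and AT1G33055 were 3.54-fold and 3.39-fold higher in met. AT1G51850, a receptor-like kinase gene with leucine-rich repeats, fell from 107.2 ± 22.4 to 32.65 ± 7.29 (log2 -1.72, adjusted p = 0.00221). AT3G60420 fell from 370 ± 39.8 to 114.7 ± 24.7 (log2 -1.71, adjusted p = 0.00059). AT2G23910 (log2 -1.60) and the chitinase family gene AT4G01700 (log2 -1.56) followed. AT1G15010 had the highest signal of these genes and fell from 1051 ± 120 to 490 ± 61.1 (log2 -1.10, adjusted p = 0.00124). AT1G06000, which encodes a flavonol rhamnosyltransferase, fell from 118.8 ± 13.8 to 58.6 ± 3.11 (log2 -1.01, adjusted p = 0.00221). AT1G49750 also had a log2 difference of -1.01 (adjusted p = 0.0324).

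For AT3G48640 and AT5G22555 the fum means lay below the signal of 21.1 that served as the filter, and with 16 added to each signal their log2 differences were -1.53 and -1.06. The fall of AT3G60420 was then deeper than that of AT3G48640, at -1.58. AT5G22555 passed on 7 arrays only without fum replicate 1 or 2 (adjusted p up to 0.112, log2 -2.12 to -1.38 over all omissions). AT1G33055 did not pass without fum replicate 1, met replicate 3 or met replicate 4 (adjusted p up to 0.0688, log2 -2.05 to -1.43). It read 17.2 and 10.8 on fum replicates 1 and 2, below the filter signal, and had a log2 difference of -1.20 with 16 added. AT1G49750, with a fum mean of 21.3, had -0.65 with 16 added and passed on 7 arrays only without fum replicate 4 or met replicate 2 (adjusted p up to 0.114, log2 -1.15 to -0.93).

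**Figure D1:**
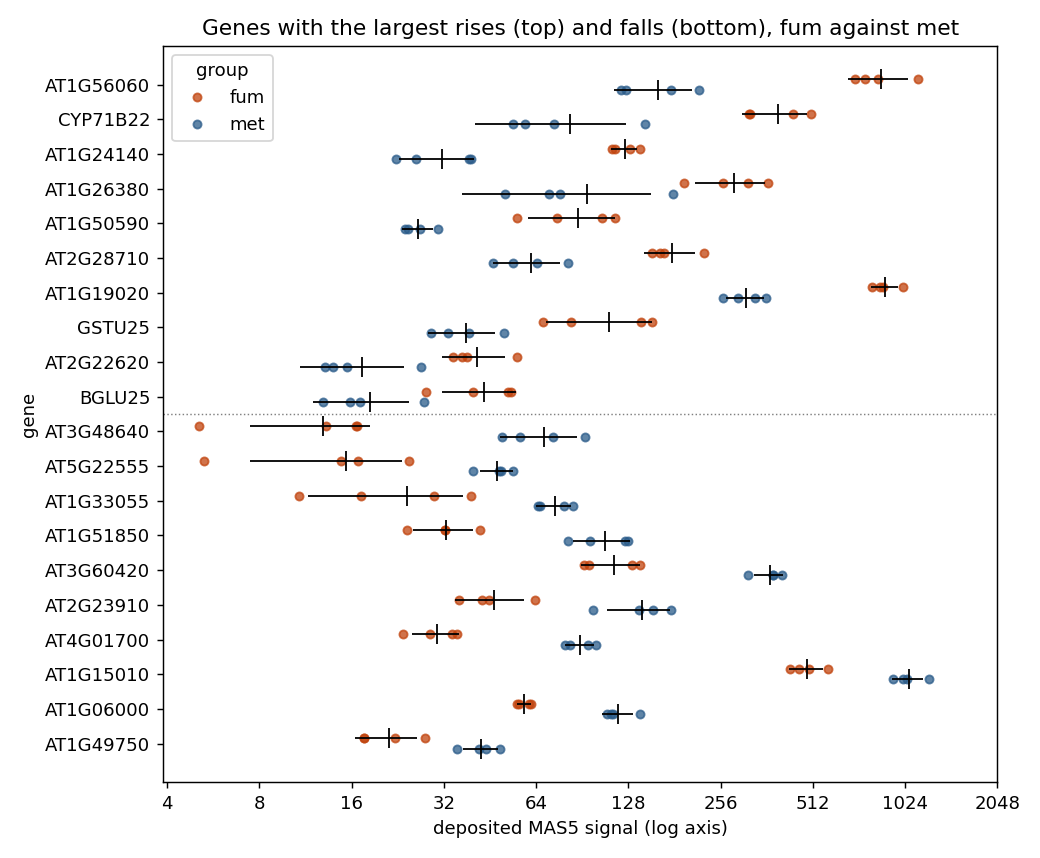
Deposited signal (horizontal log axis) of the 10 named genes with the largest rises and the 10 with the largest falls. Coloured points are the 4 fum and 4 met arrays, and black ticks with bars are the group means ± SD. By the rule that chose these genes, the fum and met points do not overlap, as for AT1G56060 with means of 855 in fum and 160.4 in met.

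Of 13647 probe sets tested with limma, 351 passed an adjusted p of 0.05, with 200 higher and 151 lower in fum. A difference of at least 1 on the log2 scale was reached by 70 of them, 47 higher and 23 lower. Taken as 1 probe set per gene, 163 of 7471 tested genes passed, with 105 higher and 58 lower. The smallest adjusted p was 0.000200 and 2437 probe sets had an unadjusted p below 0.05. All 4 arrays of one group lay on one side of all 4 of the other for 1693 probe sets, or 12.4% of those tested. Chance gives 2.86% on average over all divisions of the arrays, and single divisions were not compared on this measure. At an unadjusted limma p below 0.05 other divisions gave 140 to 1993 probe sets, so 1 chance division can lie far from the average. Of the 351 probe sets, 181 had no gene in the annotation used here. The largest differences among these, chosen outside the naming rule after their values were seen, were in probe sets 264648_at and 265221_s_at. 264648_at had 213 ± 33.0 signal units in fum and 8.8 ± 5.74 in met (log2 4.96, adjusted p = 0.00124). 265221_s_at had 91.3 ± 14.4 and 10.5 ± 2.58 (log2 3.13, adjusted p = 0.000200). Probe sets 250286_at and 257382_at fell most, with log2 differences of -2.87 and -2.81 and fum means of 11.3 and 16.9. In each of these 4 probe sets the lower group lay below the filter signal, so the size of the difference is uncertain. With 16 added to each signal, 264648_at had 3.23, 265221_s_at 2.01, 250286_at -1.70 and 257382_at -1.88. The count of 351 became 175 without fum replicate 1, 168 without fum replicate 3, 112 without fum replicate 4, 154 without met replicate 3 and 151 without met replicate 4. The count of 163 genes became 75, 71, 49, 68 and 59 without the same arrays. Without fum replicate 2, 89 probe sets and 32 genes were lower in fum.

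Among the gene lists fixed before the data were examined, 5 of 63 tested members rose and 0 fell. At an unadjusted limma p below 0.05 there were 9 higher and 9 lower. Of the 4 tested detoxification genes, GSTU25 rose as above and the glucosyltransferase gene UGT73B5 rose 1.82-fold, from 44.5 ± 5.74 to 81.2 ± 11.5 (SD, n = 4, limma adjusted p = 0.0131). The transporter genes DTX4 (AT2G04070) and DTX3 did not pass, with log2 differences of -0.48 and -0.55. Adjusted over the list alone, 2 detoxification genes were higher and 2 were lower. All 4 tested genes of the endoplasmic reticulum stress list had higher means in fum, and 1 passed. It was the chaperone gene ERDJ3B, at 592.5 ± 58.2 in fum and 418 ± 32.3 in met (1.42-fold, adjusted p = 0.0253). The calreticulin gene CRT1B had a 1.28-fold difference (adjusted p = 0.0533) and the transcription factor gene BZIP60 a 1.18-fold difference (adjusted p = 0.282). Adjusted over the list alone, ERDJ3B and CRT1B passed, which makes 2 of 4. CRT1B also passed over all probe sets without met replicate 1 (adjusted p = 0.0441). IGPS (AT2G04400), an enzyme of tryptophan synthesis and the only tested member of its list, rose 1.56-fold to 857 ± 174 (limma adjusted p = 0.0467). Its unadjusted p was 0.0011, which adjustment over a list of that gene alone leaves unchanged.

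Of 6 tested vacuolar processing enzymes and papain-like or cathepsin proteases, 1 rose, and the same 1 passed adjusted over the list alone. It was the cathepsin B gene CATHB3 (AT4G01610), at 253 ± 15.6 in fum and 172.3 ± 24.2 in met (SD, n = 4, 1.48-fold, limma adjusted p = 0.0305). ALPHA-VPE had a 1.91-fold difference with wide spread (adjusted p = 0.178), and GAMMA-VPE a log2 difference of -0.22 (adjusted p = 0.225). The list as a set did not pass (camera adjusted p = 0.296). None of the 7 tested genes of sphingolipid metabolism passed, and 1 had an unadjusted p below 0.05. Of these 7 genes, 6 had higher means in fum, with a list mean log2 difference of 0.18. The glucosylceramide synthase gene GCS (AT2G19880) had a 1.37-fold difference (adjusted p = 0.0909, and 0.0305 adjusted over the list alone). The sphingosine-phosphate lyase gene DPL1 stood at 1.22-fold (adjusted p = 0.354) and TSC10B at 1.17-fold (adjusted p = 0.603). The set did not pass with camera (adjusted p = 0.195), whereas fry, which tests the set against no change between groups and not against other genes, gave an adjusted p of 0.0429.

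None of the 12 tested autophagy genes passed, and none passed adjusted over the list alone. At an unadjusted p below 0.05, 1 was higher and 1 lower. ATG8E, a gene for an autophagosome membrane protein, had a log2 difference of -0.44 (limma adjusted p = 0.127) while ATG8A had 0.36 (adjusted p = 0.252) and ATG8H 0.25 (adjusted p = 0.436). Means were higher in fum for 9 of the 12, and the set did not pass (camera adjusted p = 0.330). With an estimated correlation, the adjusted p of the 3 sets tested was 0.557 for the proteases, 0.318 for sphingolipid metabolism and 0.619 for autophagy. No set passed with camera at an unadjusted p below 0.05 either, a count of 0 of 3, and 1 of 3 passed with fry.

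UGT73B5 did not pass without fum replicate 4 (adjusted p = 0.0600). ERDJ3B and CATHB3 did not pass without fum replicate 1, 3 or 4 or without met replicate 3 or 4, with adjusted p up to 0.0939 and 0.1045. IGPS passed on 7 arrays only without fum replicate 2 or met replicate 2 (adjusted p up to 0.148).

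The remaining lists held no gene that passed. In them WRKY22, GRX480, CML38, ROF2 and RCA, each lower in fum, had an unadjusted limma p below 0.05. Adjusted over the list alone, GRX480 passed. ROF2 and RCA were the only tested members of their lists, where that adjustment leaves p unchanged. Of 4 defence WRKY and pattern-triggered genes, WRKY22 had a log2 difference of -0.31 (limma adjusted p = 0.153), WRKY6 0.43 (adjusted p = 0.438) and WRKY53 -0.29 (adjusted p = 0.615). Of 2 tested salicylic acid pathway genes, the glutaredoxin gene GRX480 had -0.35 (adjusted p = 0.127, and 0.0184 adjusted over the list alone) and SAG101 0.25. Of 4 mitochondrial dysfunction markers, CML38 had -0.43 (adjusted p = 0.181), the alternative dehydrogenase gene NDB2 0.25 (adjusted p = 0.314) and HSP23.5 (AT5G51440) -0.12. The only tested heat shock gene, ROF2 (AT5G48570), had -0.49 (adjusted p = 0.0661, and 0.00223 unadjusted). Of 4 senescence and sugar starvation genes, PPDK had -0.94 with an SE of 0.48 (adjusted p = 0.336) and IVD -0.21. The reactive oxygen genes GR1 and ZAT10 (STZ) had -0.15 and -0.14, and the ethylene gene EIN3 had 0.06. In the cell cycle list, AUR1 had -0.14 and MCM7 (PRL) 0.02, and in the cell wall list EXPA4 had 0.03. Of 3 phenylpropanoid genes, CCR2 had 0.21, HCT -0.05 and DFR 0.11. The only tested developmental cell death marker, SCPL48, stood at 460 ± 6.17 in fum and 454 ± 55.4 in met (SD, n = 4, log2 0.03). RCA, the only tested marker of chloroplast-bearing leaf cells, had -0.29 (adjusted p = 0.155, and 0.0139 unadjusted).

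Of 4 housekeeping reference genes, none passed or had an unadjusted limma p below 0.05. UBC21 (PEX4) stood at 234 ± 26.7 in fum and 233 ± 18.3 in met (SD, n = 4). TUB6 had a log2 difference of 0.10, TIP41 (AT4G34270) -0.07 and SAND (AT2G28390) -0.26. Centring each array on its median turned the sign of the near-zero values of MCM7, EXPA4 and SCPL48, and quantile normalization that of HCT. The lists of metacaspases, regulators of cell death, jasmonate genes, auxin and cytokinin response genes, tracheary elements, root and root hair cells, and embryo and seed cells, 7 in all, had no member tested here.

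Single arrays moved the log2 differences of several list genes that did not pass by more than 1.5 times. Without fum replicate 2, PPDK stood at -0.32, IVD at -0.037, DPL1 at 0.15, TSC10B at 0.35, GR1 at -0.050 and SAND at 0.024. Without met replicate 1, WRKY6 stood at 0.092, CML38 at -0.26, NDB2 at 0.15, TSC10B at 0.089, SAG101 at 0.45 and ZAT10 at -0.40. Without met replicate 3, ATG8A stood at 0.24, WRKY53 at -0.11 and ZAT10 at -0.024. Without met replicate 4, ATG8H stood at 0.17, WRKY53 at -0.48 and SAG101 at 0.12, and without fum replicate 3, AUR1 at -0.049 and GR1 at -0.23. The values of MCM7, EXPA4, SCPL48, EIN3, TUB6, TIP41, HCT, DFR and UBC21, all nearer to 0, moved as much with several arrays. With 16 added to each signal, PPDK stood at -0.61.

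Other settings ended or added calls among the named genes. With the replicate number as a block, AT1G26380, AT2G22620, BGLU25, AT5G22555, AT1G33055, AT1G49750, UGT73B5, ERDJ3B, IGPS and CATHB3 did not pass. Centring each array on its median ended the calls of AT2G22620, BGLU25, AT5G22555, UGT73B5, ERDJ3B, IGPS and CATHB3, and leaving out the intensity trend those of AT1G26380, BGLU25, AT5G22555, AT1G33055, ERDJ3B, IGPS and CATHB3. With no filter AT2G22620, BGLU25, AT5G22555, AT1G49750 and IGPS did not pass, after quantile normalization AT2G22620 and AT5G22555, and in the robust fit AT1G26380. Within the 5 arrays with high 25S signal AT1G26380, GSTU25, AT2G22620, BGLU25, AT5G22555, AT1G49750, UGT73B5, ERDJ3B and IGPS did not pass, and within the 3 low arrays, with 1 fum array, only AT1G56060, AT1G19020, AT1G51850 and AT1G15010 of the 24 passed.

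Array weights added calls for CRT1B, BZIP60 and GCS, higher in fum, and for WRKY22, DTX4 and ROF2, lower in fum, so the count of 0 list genes that fell does not hold under that setting. With the 25S signal as a covariate CRT1B passed as higher and ATG8E and ROF2 as lower. With low against high 25S signal as a block CRT1B, GCS and ATG8A passed as higher and ROF2 as lower, and with the filter at the 60th percentile CRT1B passed as higher.

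**Figure D2:**
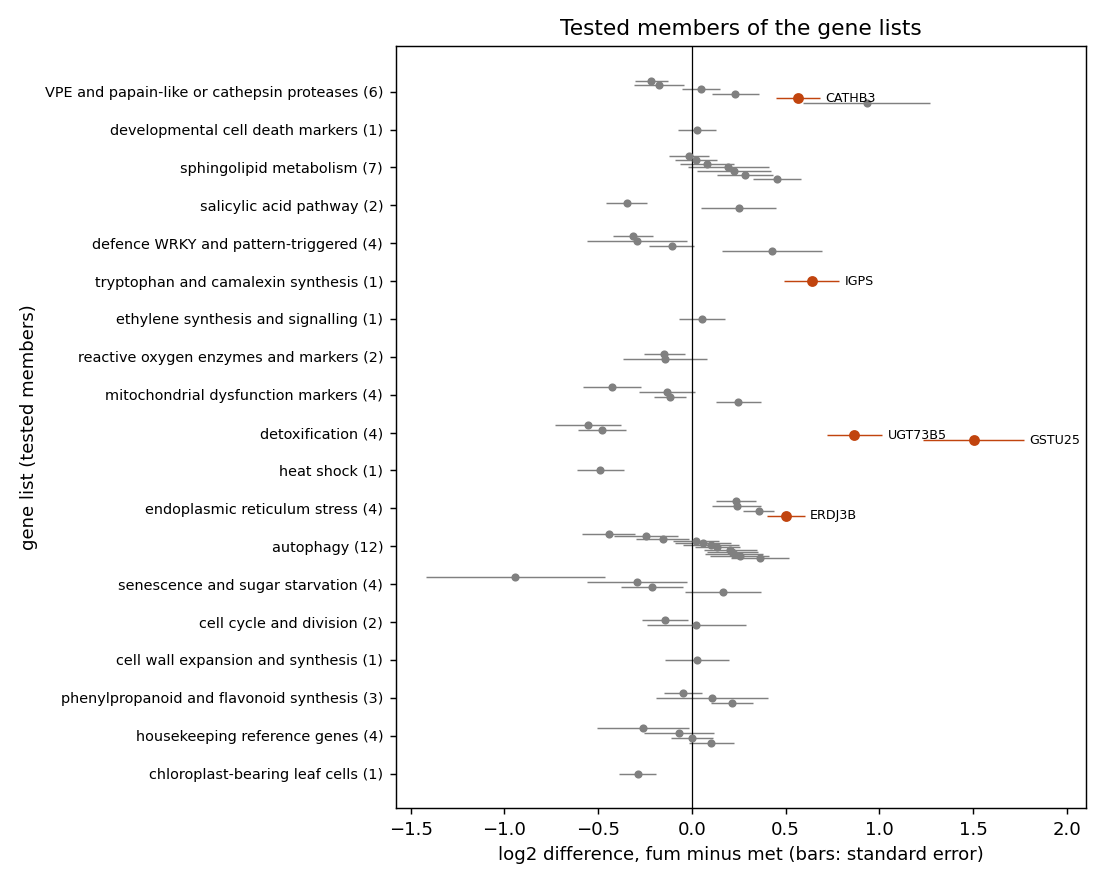
Log2 difference between fum and met (horizontal axis, positive where fum was higher) of each tested member of 19 gene lists, with the number tested in brackets. Bars are standard errors from limma and coloured points are genes with an adjusted p below 0.05. The 5 coloured points all lie to the right of 0, from ERDJ3B (1.42-fold) to GSTU25 (2.83-fold), and no gene with a negative difference is coloured.

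The arrays differed in control signals. The signal ratio of the 3′ to the 5′ actin control was 12.01 on met replicate 1 and between 1.92 and 2.39 on the other arrays, and the groups as a whole were not separated (exact permutation p = 0.371, two-sided). The 25S ribosomal RNA probe set read 157.6 on fum replicate 3, 824 on met replicate 1 and 1305 on met replicate 2, and 2806 to 4491 on the other 5 arrays (exact permutation p = 0.743). Geometric mean signals of plastid-encoded genes ran beside it, from 61.5 on fum replicate 3 to 402 on met replicate 3. The spiked-in hybridization controls averaged 343 ± 88.1 in fum and 545 ± 98.6 in met (SD, n = 4), a 1.60-fold difference with an exact permutation p of 0.0571, where the smallest p that 4 arrays against 4 allow is 0.0286. After adjustment over the 11 quality measures this p was 0.471. Without met replicate 1 the count of changed probe sets was 363, close to the 351 of all arrays. Within the 3 arrays with low 25S signal the count was 45, within the other 5 it was 148, and with low against high 25S signal as a block it was 789, a division chosen after seeing the data. Only 1 of the 3 low arrays is fum. Whether the fum difference itself differed between low and high arrays rests on that single array and stays open. The count within the low arrays rests on it too, and assumes that it varied like the others.

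**Figure D3:**
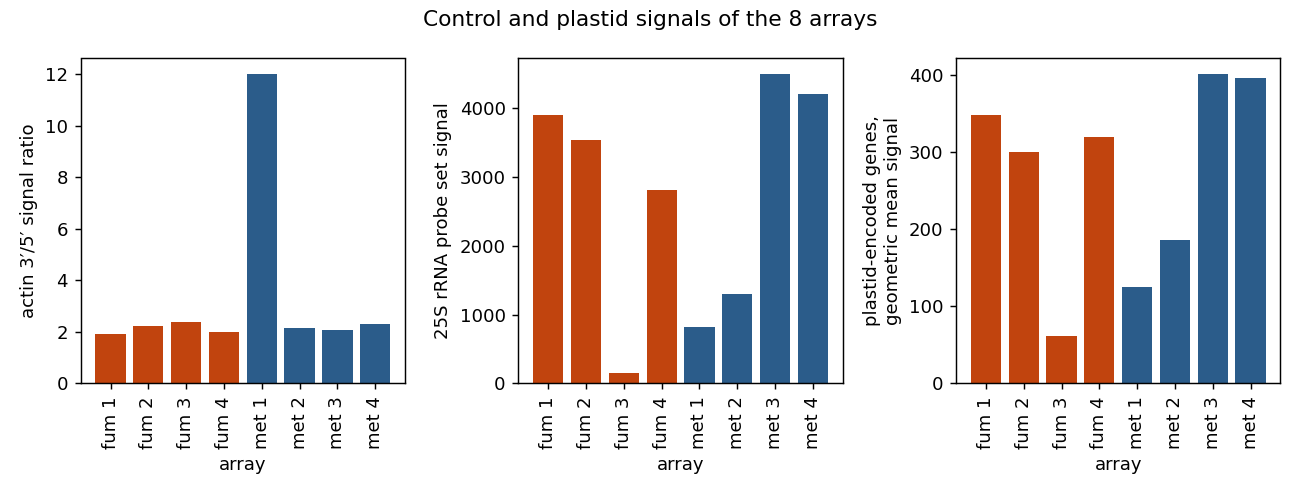
Bars give, for each of the 8 arrays (4 fum, 4 met), the ratio of 3′ to 5′ actin control signal, the 25S ribosomal RNA signal, and the geometric mean signal of plastid-encoded genes, each on a linear axis from 0. Met replicate 1 has an actin ratio of 12.01, and fum replicate 3 has the lowest 25S (157.6) and plastid (61.5) signals.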

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

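The tests on 25S signal in this part, and the bound put on the count without met replicate 1, were chosen after the first results had been seen, while leaving out each array in turn was planned. In 10 of 144 checked groups of 4 arrays, 1 array stood far from the other 3, where chance gives about 7.2.

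Met replicate 1 had an actin 3′ to 5′ ratio of 12.01 (2.08 to 2.32 on the other met arrays) and a ubiquitin ratio of 2.94 (1.44 to 1.58). Fum replicate 3 had a 25S ribosomal RNA signal of 157.6 (2806 to 3901 on the other fum arrays), a mitochondrion-encoded mean signal of 51.3 (123 to 137) and a plastid-encoded mean signal of 61.5 (300.2 to 349). Among named genes, UGT73B5 read 53 on met replicate 2 (40.9 to 42.7 on the others), SAND (AT2G28390) 54.3 on fum replicate 2 (116.3 to 122.5), CML38 990 on met replicate 1 (596 to 643), PPDK 61.7 on met replicate 3 (66 to 66.9) and TSC10B 33.8 on fum replicate 2 (47 to 48.3).

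The count of 351 probe sets called between fum and met argues against chance in how the arrays were divided. It does not exclude chance, since only 35 splits exist. Only 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, called as many, and the highest of the other splits called 0 with limma. At an unadjusted p below 0.05 the other splits gave 140 to 1993 probe sets against 2437, so large counts at that limit also arose under other divisions. For the 70 probe sets with a log2 difference of at least 1, also 1 of 35 splits gave as many and the highest other gave 0. For gene lists the real split called 0 and the highest other called 2, so there is no list call for chance to explain, and a count of 35 of 35 splits was fixed beforehand.

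The 25S signal and the 3′ to 5′ ratios could have carried part of the difference between groups, since fum replicate 3 and met replicate 1 stand apart in them. With the log2 25S signal as a covariate, 523 probe sets were called afresh, against 351 without it. Without met replicate 1, 363 were called afresh on the other arrays, and 278 of the 351 were among them. The number of calls therefore did not rest on met replicate 1. The 25S signal did not separate the groups (exact permutation p = 0.743, two-sided), so that covariate could hardly remove calls and decides little. Either measure may add to the spread. The test first written down, the share of the 351 with an unadjusted p below 0.05, decides nothing, since it was 100% in nearly every setting. A difference between the fum and met cultures stays open as the source, and the labels do not say what the groups received. The labels do not describe handling, and of the 11 quality measures the hybridization controls came nearest to separating the groups, 1.60-fold higher in met (exact permutation p = 0.0571, adjusted p = 0.471), which leaves a difference in handling open.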

How the results depend on the processing

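The settings based on 25S ribosomal RNA signal were added after seeing the data. Of the 351 called probe sets, 351 were called again with the 25S signal as a covariate, 278 without met replicate 1, 110 without fum replicate 4 and 21 within the 3 arrays with low 25S signal (1 fum array there, assumed to vary like the others). None changed direction in any setting that tested it (313 of the 351 were tested with the filter at the 60th percentile). However, 349 of the 351 had groups that did not overlap. For these, leaving out an array or comparing within the low or high 25S arrays could not change the direction. The numbers that follow are probe sets (higher and lower in fum), then genes (higher and lower in fum). Centring each array on its median gave 116 (64 and 52) and 46 (26 and 20). Leaving out the intensity trend gave 164 (102 and 62) and 77 (51 and 26). Array weights gave 1323 (738 and 585) and 655 (385 and 270), with 111 at a log2 difference of at least 1. The 25S signal as a covariate gave 523 (292 and 231) and 251 (154 and 97). Low against high 25S signal as a block gave 789 (465 and 324) and 391 (245 and 146), with 112 at a log2 difference of at least 1. Within the 3 low arrays there were 45 (14 and 31) and 30 (8 and 22), with 40 at that difference, from fewer samples. Within the 5 other arrays there were 148 (95 and 53) and 71 (49 and 22). With 16 added to each signal, 46 of 367 reached a log2 difference of at least 1. Groups did not overlap for 1693. Leaving out 1 array gave 112 to 415 probe sets (65 to 256 higher, 47 to 159 lower, 50 to 97 at a log2 difference of at least 1) and 49 to 184 genes (29 to 123 higher, 20 to 61 lower). Fewer samples may account for part of the lower counts where arrays were left out, but the cause was not tested. Quantile normalization, no filter, the filter at the 60th percentile and the robust fit stayed within 1.5 times of all counts (274 to 391 probe sets). The 3 gene lists tested as sets had positive means in every setting and were not called by camera in any, while fry called 1 of them, sphingolipid metabolism (adjusted p = 0.0429). Signal limits the dim part of the table, since probe sets with mean signal under 21.1 were not tested.

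The replicate number as a block gave 115 probe sets (65 and 50) and 49 genes (30 and 19). Deviations from the group mean correlated between fum and met arrays of the same number at -0.17, -0.30, -0.47 and 0.14. Only fum replicate 4 correlated best with its own number, so no pairing by number was seen, though these correlations cannot exclude it.

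Every gene that changed sign was uncalled, and the cause was not tested. Not all were near 0 on all 8 arrays, where DPL1 had a log2 difference of 0.28, SAND -0.26 and IVD -0.21. Log2 differences under those settings were as follows. Array weights gave 0.10 for TIP41, -0.098 for DFR, -0.016 for EIN3, -0.081 for EXPA4 and -0.30 for PRL. Centring on the median gave -0.0022 for EXPA4, -0.0066 for PRL and -0.0025 for SCPL48. Quantile normalization gave 0.050 for HCT, and 16 added to each signal gave 0.00015 for PEX4. Low against high 25S signal as a block gave 0.066 for TIP41, -0.031 for DFR, -0.064 for EXPA4, 0.035 for PEX4 and -0.18 for PRL. Within the 5 arrays with high 25S signal, TIP41 was at 0.061, DFR at -0.051, EXPA4 at -0.098, HCT at 0.039 and PRL at -0.32. Within the 3 low arrays, SAND was at 0.14, TIP41 at 0.076, HSP23.5 at 0.0051, DPL1 at -0.031, EXPA4 at -0.0036, GR1 at 0.085, IVD at 0.030, PEX4 at 0.16, ZAT10 at 0.039 and SCPL48 at -0.023. Leaving out 1 array gave ranges across 0 for SAND (-0.38 to 0.024), TIP41 (-0.21 to 0.045), DFR (-0.12 to 0.29), EIN3 (-0.051 to 0.13), EXPA4 (-0.15 to 0.13), HCT (-0.13 to 0.026), PEX4 (-0.062 to 0.067), PRL (-0.17 to 0.21) and SCPL48 (-0.041 to 0.078). For plastid-encoded and mitochondrion-encoded genes the ranges were -0.54 to 0.39 and -0.45 to 0.11 over the same omissions. Without fum replicate 3 both means were positive, and the plastid-encoded mean was also above 0 without met replicate 3 (0.022) or met replicate 4 (0.016).

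Of the 24 named genes that passed, 13 passed in each omission of 1 array. The mean of the 15 COPI and SEC61 genes ranged from 0.29 to 0.39 over all settings, with an unadjusted camera p of at most 0.00274. That set was chosen from called genes, so this p is no independent evidence of a difference.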

Other observations

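The lists and symbol families in this part, the relations with 25S signal and the test of a difference between cultures in the COPI and SEC61 genes were chosen after the first results had been seen, so no list here is independent evidence of its direction. The tests without met replicate 1 and on neighbouring genes were set before their results were seen. Among genes called higher in fum were coat and translocation components of the early secretory pathway. In the COPI coat, which forms vesicles at the Golgi apparatus, 3 of 9 tested genes rose: AT3G15980 (1.66-fold, limma adjusted p = 0.00327), AT1G62020 (1.503-fold) and AT2G21390 (1.499-fold). In the SEC61 translocon, through which proteins enter the endoplasmic reticulum, 2 of 6 rose: AT3G60540 (2.28-fold, adjusted p = 0.00327) and AT1G29310 (1.78-fold). Of the 15 genes together, 14 had higher means in fum, with a mean log2 difference of 0.35. Camera gave adjusted p = 0.00121 for COPI and 0.00383 for SEC61 over 31 added sets, and adjusted p = 0.180 for each with an estimated correlation. The COPII coat, which carries vesicles out of the endoplasmic reticulum, had 0 called genes of 14, with 4 higher at an unadjusted limma p below 0.05 (camera adjusted p = 0.0173, adjusted p = 0.600 with an estimated correlation), and its unadjusted p was 0.0671 without met replicate 1. In the added oligosaccharyltransferase list, the tested genes AT2G01720 and AT1G76400 were not called, with log2 differences of -0.14 and 0.007.

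Cytosolic ribosomal protein genes had lower means in fum for 36 of 38 tested, by a mean log2 difference of -0.18 (-0.058 after quantile normalization), and 1 of them, AT2G17360, fell (adjusted p = 0.0460). Camera with the preset correlation gave an adjusted p of 2.33e-09 for this set, but adjusted p = 0.547 with an estimated correlation of 0.47, and the exact permutation p of the list mean was 0.0571. Of 25 families defined by gene symbol, CYP, SEC and NET passed as higher in fum, and SCPL and NRPB as lower. Their camera adjusted p lay between 0.00666 and 0.0419 with the preset correlation and between 0.180 and 0.556 with an estimated one. The mean log2 signal of NRPB genes was 8.88 on met replicate 1 and 8.36 to 8.46 on the other met arrays. Among CYP genes, CYP71B22 and CYP71B24 rose (log2 2.34 and 1.10), 2 of 6 tested. Other genes that rose were the mitochondrial and peroxisomal fission gene BIGYIN (log2 0.56), the dynamin-like gene DL1B (log2 0.57) and the glucosyltransferase genes UGT73B4 (log2 0.78) and GT72B1 (log2 0.98). The chalcone isomerase-like gene CHIL (log2 -0.82), the defensin-like gene PDF2.1 (log2 -0.94) and the nitrate transporter gene NRT2.5 (log2 -0.91) fell.

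For the 15 COPI and SEC61 genes, weak 5′ signal on met replicate 1 was weighed first. Without that array their mean log2 difference was 0.37, not lower than the 0.35 with all arrays, which argues against it. An influence of signal level was not excluded, since a set chosen from called genes stands above random sets by its choice. A difference between the fum and met cultures stays open, and no value here tests it fairly. The mean of all 15 had an exact permutation p of 0.0286, the smallest possible, but the set was chosen from called genes. The 10 members not called individually had a mean log2 difference of 0.13, with 9 higher in fum (exact permutation p = 0.0571, camera p = 0.0423), but leaving out the called members weakens that result.

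Pairs of called genes at most 3 coding genes apart and with the same direction numbered 3: UGT73B5 with UGT73B4, AT3G13650 with AT3G13660, and CYP71B22 with CYP71B24. Random placement of the 162 called genes among 7230 tested genes, in the order of the TAIR10.1 assembly, gave as many pairs with a permutation p of 0.222, so clustering of calls along the chromosomes was not seen. UGT73B5 and UGT73B4, like CYP71B22 and CYP71B24, belong to one subfamily, and signal shared between related sequences could contribute. Probe sets with several genes in the annotation had been left out beforehand, which made a low share of marked probe sets likely. No pair, 0%, held a probe set marked as shared between genes. Such marks cover only sharing known when the array was designed, so cross-hybridization cannot be told apart from parallel change here.

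Across the 8 arrays, log2 25S ribosomal RNA signal went with the log2 mean signal of plastid-encoded genes (r = 0.991, exact permutation p = 0.000174, rho = 0.976, exact permutation p = 0.000397, and r = 0.968 without the 2 arrays farthest from the median). It also went with that of mitochondrion-encoded genes (r = 0.970, exact permutation p = 0.000124, rho = 0.976, exact permutation p = 0.000397, and r = 0.898 without those arrays). Both had an adjusted p of 0.00026 over 3 relations. The third, with the actin 3′ to 5′ ratio, had r = -0.34 (exact permutation p = 0.201), rho = -0.52 (exact permutation p = 0.197) and r = -0.01 without those arrays. As a set, the 60 plastid-encoded genes had a mean log2 difference between fum and met of -0.21 (camera adjusted p = 0.148) and the 13 mitochondrion-encoded genes -0.22 (camera adjusted p = 0.148). Without fum replicate 3 these means were 0.39 and 0.11, and over all omissions of 1 array they ranged from -0.54 to 0.39 and from -0.45 to 0.11. With camera at the preset correlation and an unadjusted p below 0.05, the plastid-encoded set passed in either direction, higher in fum without fum replicate 3 and lower without met replicate 1. It also passed as lower with low against high 25S signal as a block (mean -0.67) and within the 3 low arrays, of which 1 is fum (mean -1.31), but not with the 25S signal as a covariate (mean 0.036). The mitochondrion-encoded set passed as lower without met replicate 1, with the block (mean -0.51) and with each array centred on its median (mean -0.25). It did not pass without fum replicate 3. With an estimated correlation on all 8 arrays, camera adjusted p was 0.949 for plastid-encoded genes (correlation 0.67) and 0.847 for mitochondrion-encoded genes (correlation 0.84). No direction is claimed for either set.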
